A study of Homo sapiens with 18 samples.

How the data were processed

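Primary human glomerular endothelial cells were cultured with 10% serum from patients with neuroblastoma in tandem autologous stem cell transplantation, either with active transplant-associated thrombotic microangiopathy (TA-TMA) or time-matched without it, per the labels. The 18 libraries form 4 groups, with 4 libraries of serum without TA-TMA and 5 of TA-TMA serum at each of 24 h and 72 h. The treatment tag of each library gives 24 h or 72 h, while the treatment protocol in the labels gives 72 h for all of them, and the tag was used. A culture in medium without human serum is named in the design text and was not analysed here. The labels do not say whether a serum was used in more than 1 culture, so p-values measure the spread between these libraries.

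Total RNA was made into directional libraries with a NEBNext Ultra II kit, per the labels' protocols. STAR, Salmon and DESeq2 and the build hg19 are named in the submitters' processing notes, and their versions are not given in the sources used here. The authors deposited 2 tables, 1 per time, each with 27914 gene symbols and a normalized signal per library. The authors' names for the deposited tables call the values DESeq counts, and the values themselves look like gene counts divided by a factor per library and, for most genes, a further factor per gene. The tables were normalized apart, so levels were tested within a table only, and the planned comparisons of 72 h with 24 h within each kind of serum were not run. The difference between the serum effects of both times is a difference of differences within tables and was tested. All values of genes seen in 1 library of a table were whole multiples of a library step, within a tolerance of 0.01, which gave the value of 1 read and so an estimated depth. Among the other low values only 51.5% to 73.9% were whole, so whole reads were not recovered and no count test was run. Estimated depth was 20.8 to 28.8 M reads per library. Its mean difference, TA-TMA minus the other serum, was 0.673 M at 24 h (exact permutation test, two-sided, p = 0.683) and -0.126 M at 72 h (p = 0.937, same exact test). No pair of libraries of a group differed by as little as sampling noise, since the lowest chi-square per degree of freedom was 3.61, and log2 values of library pairs correlated at 0.974 to 0.991.

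The plan had been a count test, and the unit made limma the main tool (limma 3.58.1, R 4.3.3). Genes with a value of at least 10 in at least 4 libraries were kept, which left 13188 genes at 24 h, 13125 at 72 h and 12961 in the fit of both times. Log2(value + 1) was fitted with a mean-variance trend and a robust variance prior, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates those of low genes. A set of 40 gene lists was fixed before the data were examined, and lists with at least 3 tested members were compared with the other genes by camera with a preset correlation of 0.01 and again with an estimated correlation. The fry test asked whether a list's genes moved, on balance, one way, without comparing them with other genes. Named genes followed a rule fixed at the same time. They were the 8 largest changes in each direction among genes past the threshold with a mean of at least 1 CPM (here per M of a library's normalized total), or where fewer passed, up to 4 of smallest p, up to 4 members of each list with a passing member or a camera call, and 1 member in any case of the adhesion, complement, coagulation, glycocalyx and interferon lists. For the difference between times they were the 5 largest in each direction and up to 3 members of each list called. Y-linked genes, XIST and genes with no symbol were skipped, and some genes that the rule names are not reported here.

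The fits were tested on simulated tables with known fold changes in 200 genes. At 24 h, 67.0% of genes changed 1.5-fold and 86.0% of those changed 2-fold were called among 13186 genes, with 8 false calls. At 72 h the shares were 67.0% and 81.0% among 13106 genes, with 11 false calls. With a change at 72 h alone, the fit of the difference between times called 63.3% and 81.6% among 12921 genes, with 12 false calls. False calls made up 4.97% of the calls at 24 h, 6.92% at 72 h and 7.79% for the difference between times. With no change simulated, limma called 0 genes and camera 0 lists at either time. Genes were simulated independently of each other, so this does not give the rate of chance calls in the real libraries. There, 14 of 99 other splits of the 24 h libraries into groups of the same sizes called any gene, and 13 of 99 at 72 h. These splits called a median of 7 lists at 24 h. At 72 h the median was 6 lists. These are calls by camera with the preset correlation.

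Alternatives were filters, thresholds, each library left out, all 18 libraries in 1 fit and, after seeing the data, other pseudocounts, scalings, quality weights, a variance prior that is not robust, and removal of trends with transcript length and GC content. Length and GC content came from a GENCODE annotation of a newer build by gene symbol, and covered 97.9% of genes tested at 24 h and 98.0% at 72 h. Count models, voom weights and surrogate variables were chosen beforehand as further settings and were not run. Count models and voom weights need raw counts. Mitochondrially encoded genes were not analysed here. Genes with near-identical copies, the metallothionein and HLA families among them, and read-through names share reads and their values are uncertain.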

Results

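TA-TMA is a small-vessel disease in which injured endothelium and platelet thrombi damage the kidney after stem cell transplantation. To ask whether serum from patients with it changes gene expression of glomerular endothelium, RNA was sequenced from primary human glomerular endothelial cells cultured for 24 h or 72 h with 10% patient serum. Each time had 4 libraries of serum without TA-TMA and 5 of TA-TMA serum, with 20.8 to 28.8 M estimated reads. Between 15483 and 16047 genes were above 0 in 17 of the libraries, and 17104 in TA-TMA library 17 at 72 h. That library had 1047 genes seen in no other library of its table, against at most 132 in the other 72 h libraries, and its results are named where they matter.

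At 24 h no gene passed the adjusted threshold, and the genes named here are those of smallest p or in a called list. HNMT, which inactivates histamine, was at 77.8 ± 2.74 normalized counts (SD, n = 4) without TA-TMA and 121 ± 6.53 (n = 5) with it, a log2 fold change of 0.63 (SE 0.10, limma adjusted p = 0.233). The antigen-presenting molecule HLA-B was at a log2 fold change of 0.42 (SE 0.07, adjusted p = 0.276). The lysosomal glycoprotein gene GPNMB was at 0.58 (SE 0.10, adjusted p = 0.264). In the other direction the signalling adaptor GRB14 was at -0.41 (SE 0.07, adjusted p = 0.233), the cytokine receptor IL7R at -0.76 (adjusted p = 0.402). The zinc-binding metallothioneins MT1E and MT2A were at -0.21 and -0.22 (both adjusted p = 0.424). With limma 0 of 13188 genes passed, 1010 had an unadjusted p under 0.05 where 659 would by chance. That excess was not stable. The number was 666 without library 2 (no TA-TMA) and 628 with all 18 libraries in 1 fit. Leaving out any other library gave 757 to 1343. The count of passing genes was also 0 under every other limma setting tried.

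Gene lists at 24 h leaned one way more than other genes by camera for 12 of 38 lists. No call held with an estimated correlation, where 4 lists had an unadjusted p under 0.05. All 30 mitosis genes, CENPE and CENPA among them, lay below 0 (median -0.28, camera adjusted p = 1.6e-11, and adjusted p = 0.397 with an estimated correlation). All 28 S phase genes did as well (median -0.21, adjusted p = 5.4e-10, and 0.397 with an estimated correlation). Among type I interferon genes, which are switched on by antiviral signalling, 29 of 31 lay above 0 with IFIT3 at 0.62 and IFIH1 at 0.45 (median 0.30, adjusted p = 4.3e-08, and 0.397 with an estimated correlation). Interferon-gamma and antigen presentation genes had 16 of 19 above 0, with TAP1 at 0.25 and HLA-C at 0.22 (median 0.18, adjusted p = 9.7e-10, and 0.182 with an estimated correlation). Adjusted over the list alone 8 of these 19 were higher, against 0 over all genes tested. Of p53 targets 24 of 27 lay above 0 (median 0.09, adjusted p = 1.5e-07, and 0.182 with an estimated correlation), with TP53INP1 at 0.24. Of adhesion genes 9 of 10 did (median 0.39, adjusted p = 0.00589, and 0.397 with an estimated correlation), among them LGALS9 at 0.56 and the leukocyte receptor gene ICAM1 at 0.36. The metallothionein and zinc response list, shortened to metallothioneins below, also holds zinc transporter genes. Of its 8 tested members 1 was above 0 (median -0.22, adjusted p = 8.9e-04, and 0.183 with an estimated correlation). Of these 2 were lower adjusted over the list alone. Of TGF-beta response genes 7 of 29 were above 0 (median -0.13, adjusted p = 8.2e-05, and 0.385 with an estimated correlation), SMAD6 at -0.61 and SNAI1 at -0.36. Adjusted over the list alone 3 of these were lower. The remaining calls were cytosolic ribosomal proteins (median 0.07), oxidative stress genes (0.13) and the retinoid list (0.19) upward and cholesterol synthesis (-0.12) downward. With an estimated correlation their adjusted p was 0.397, 0.408, 0.397 and 0.466 in that order. Without library 1 (no TA-TMA) the camera adjusted p was 0.224 for oxidative stress genes, 0.115 for the retinoid list and 0.0934 for cholesterol synthesis. The retinoid call also ended without library 2, 4, 7 or 10 (up to 0.151), and the cholesterol call without library 2, 8 or 10 (up to 0.165). The named members of further lists were CFI of complement at 0.31 (adjusted p = 0.461), F3, the tissue factor gene, at 0.49 (adjusted p = 0.631) and the sulfatase SULF2 at 0.53 (adjusted p = 0.559). By the test of movement one way, fry called 3 lists at adjusted p = 0.0427: antigen presentation, p53 targets and metallothioneins.

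At 72 h most members past the threshold were lower with TA-TMA serum in the endothelial, adhesion and matrix lists and higher in the cell-cycle lists, and no camera call of a list held with an estimated correlation (lowest adjusted p = 0.196). PECAM1, an endothelial junction adhesion molecule, fell from 20804 ± 2335 normalized counts (SD, n = 4) to 11211 ± 1729 (n = 5), a log2 fold change of -0.90 (SE 0.10, limma adjusted p = 9.97e-04). VWF, the platelet-tethering glycoprotein, fell from 26338 ± 1757 to 9280 ± 3340 (-1.57, SE 0.22, adjusted p = 0.00595). The VEGF receptor gene KDR fell from 12183 ± 1206 to 8268 ± 788 (-0.56, SE 0.08, adjusted p = 0.00205). All 5 TA-TMA libraries lay below all 4 others for each of these genes. Of 13125 genes tested, 669 were higher and 784 lower, in all 11.1% of the genes. Of these 1453 genes, 108 changed by over 1 on the log2 scale, and 1109 had groups that did not overlap. Over all genes tested 13.4% did not overlap, where chance gives 1.59%.

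The endothelial identity list had 8 of 18 members lower and 0 higher (median -0.23, camera adjusted p = 1.3e-04, and adjusted p = 0.209 with an estimated correlation). It had 10 lower and 1 higher adjusted over the list alone. PLVAP, the fenestral diaphragm protein gene, was at -1.23 and the sialomucin gene CD34 at -1.81. Adhesion genes had 7 of 10 lower (median -0.53, adjusted p = 1.3e-04, and 0.196 with an estimated correlation), with 7 lower and 1 higher adjusted over the list alone. ICAM1 was at -0.87 (SE 0.10, adjusted p = 7.26e-04), and the selectins SELE and SELP, which slow rolling leukocytes, at -1.39 and -1.19. The SELE and SELP calls ended with all 18 libraries in 1 fit (adjusted p of 0.0566 and 0.10). Angiogenesis and Notch genes had 12 of 30 lower and 3 higher (median -0.30, adjusted p = 3.4e-04, and 0.196 with an estimated correlation), against 15 lower and 4 higher adjusted over the list alone. PDGFB, which recruits mural cells, was at -1.08 (SE 0.12, adjusted p = 6.66e-04) and NRP2 at -0.74. Matrix genes had 14 of 31 lower and 4 higher (median -0.29, adjusted p = 0.00124, and 0.209 with an estimated correlation), against 15 and 6 adjusted over the list alone. The basement membrane collagens COL4A1 and COL4A2 were at -0.46 and -0.43, COL18A1 at -0.52 and MMP2 at -0.56. Lymphatic endothelium markers had 4 of 5 lower (median -0.55, adjusted p = 1.3e-04, and 0.209 with an estimated correlation), among them FLT4 at -0.82 and LYVE1 at -0.61. The count was also 4 adjusted over the list alone. The LYVE1 call ended without library 11, 12 or 17 (adjusted p of 0.0567, 0.0600 and 0.0627).

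**Figure D1:**
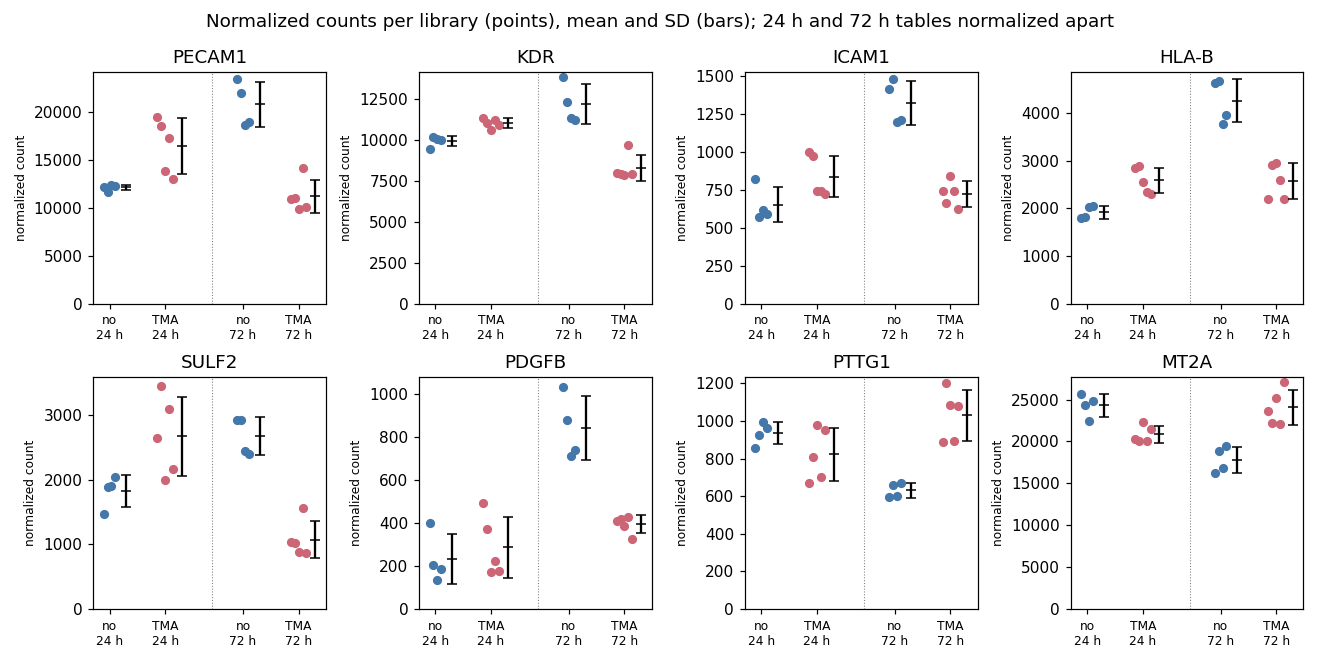
Normalized counts (vertical axes) of 8 genes in each library, as points, with the group mean and SD beside them, for serum without TA-TMA (blue) and TA-TMA serum (red) at 24 h and 72 h. The tables of both times were normalized apart, and at 72 h the 5 TA-TMA libraries lie below the 4 others for PECAM1, KDR, ICAM1, HLA-B, SULF2 and PDGFB and above them for PTTG1 and MT2A.

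In both cell-cycle lists every member past the threshold at 72 h was higher with TA-TMA serum. Mitosis genes had 23 of 30 higher and 0 lower (median 0.55, camera adjusted p = 1.9e-18, and adjusted p = 0.292 with an estimated correlation). Of these 28 were higher adjusted over the list alone. The securin gene PTTG1 rose from 631 ± 38.4 to 1029 ± 136 normalized counts (0.70, SE 0.09, adjusted p = 0.00197), and CCNB1, the mitotic cyclin gene, was at 0.67. S phase genes had 12 of 28 higher (median 0.38, adjusted p = 2.4e-11, and 0.399 with an estimated correlation), and 22 adjusted over the list alone, with E2F1 at 0.47. Heat shock genes had 6 of 20 higher (median 0.17, adjusted p = 4.7e-04, and 0.209 with an estimated correlation) and 9 higher and 1 lower adjusted over the list alone, HSPD1 at 0.44. Genes of endoplasmic reticulum stress had 4 of 30 higher (median 0.09, adjusted p = 0.0452, and 0.399 with an estimated correlation), and 6 higher and 1 lower adjusted over the list alone. The serine synthesis gene PSAT1 was at 0.39 and the cystine transporter gene SLC7A11 at 0.29. Of p53 targets 3 of 27 were lower, TP53INP1 at -0.47 (median -0.06, adjusted p = 0.0315, and 0.399 with an estimated correlation), with 3 lower adjusted over the list alone. Over all genes tested 11.1% passed. The p53 call ended without library 11, 18 or 20 (adjusted p up to 0.0897) and the endoplasmic reticulum call without library 11, 14, 16, 17 or 18 (up to 0.0841). PSAT1 did not pass without library 12 (0.0544), and SLC7A11 without 11, 12, 14, 16, 18 or 20 (up to 0.173). SLC7A11 also did not pass with all 18 libraries in 1 fit, no filter, quantile scaling or a prior that is not robust (up to 0.199).

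Interferon-gamma and antigen presentation genes had 6 of 21 lower (median -0.21, adjusted p = 4.9e-04, and 0.349 with an estimated correlation), and 6 lower and 1 higher adjusted over the list alone. HLA-B fell from 4257 ± 455 to 2570 ± 370 (-0.73, SE 0.10, adjusted p = 0.00205), and GBP2 was at -0.59. Type I interferon genes had 1 of 31 lower, IFIT2 at -0.86, with 0 adjusted over the list alone, and were not called (median -0.13, adjusted p = 0.193). IFIT2 passed in only 3 of 9 runs with a library left out, and its adjusted p reached 0.115 without library 12 and 0.0516 with no filter. TGF-beta response genes had 4 of 29 higher and 1 lower (median 0.20, adjusted p = 0.0199, and 0.399 with an estimated correlation), TGFBI at 0.72, FN1 at 0.34 and the receptor gene TGFBR2 at -0.52, against 5 higher and 1 lower adjusted over the list alone. This call ended without library 11 or 18 (adjusted p of 0.0581 and 0.0528), and FN1 did not pass without library 12 (0.0600) or with all 18 libraries in 1 fit (0.0863). Nuclear-retained RNAs were called downward (median -0.33, adjusted p = 0.0404, and 0.209 with an estimated correlation) with 0 of 6 members past the threshold by limma and 0 adjusted over the list alone. MALAT1 was at -1.14 (adjusted p = 0.120), and the list's call ended without library 11, 13 or 19 (camera adjusted p up to 0.0619).

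Lists without a camera call at 72 h still held genes past the threshold. Over all genes tested 11.1% passed, so a count near that share does not set such a list apart. Of these lists fry, which compares no list with other genes, called glycocalyx (adjusted p = 0.0136), NF-kB targets (0.0258), lipid genes (0.0241), hypoxia and glycolysis (0.00340) and epithelial markers (0.00395). In the coagulation list 4 of 28 genes were higher and 5 lower (adjusted p = 0.801), with the urokinase receptor gene PLAUR at 0.58 and TFPI2, a protease inhibitor gene, at -0.51. In the complement list 2 of 16 were lower, CLU and CFB, both at -1.07 (list adjusted p = 0.255). In the glycocalyx list 2 of 26 were higher and 5 lower (list adjusted p = 0.255), with BGN at -0.80 and the heparan sulfate-cleaving enzyme HPSE at 0.35. SULF2 of this list fell from 2678 ± 294 to 1075 ± 288 (-1.35, SE 0.15, adjusted p = 0.00188). Of cytokines 3 of 14 were higher and 2 lower, IL6 at 0.89 and CSF1 at -0.52. In the metallothionein and zinc response list 3 of 8 were higher, MT2A at 0.43. Adjusted over the list alone, coagulation had 4 higher and 6 lower, complement 2 lower, glycocalyx 3 higher and 5 lower, cytokines 5 higher and 3 lower, and metallothioneins 3 higher. ABCA1, a cholesterol exporter gene, was at -0.98 and PDK4 at -0.91. Of genes with a mean of at least 1 CPM, among the largest rises were GDF6 (2.19, SE 0.32), MEST (1.40), TSPAN8 (1.17) and SERPIND1, the heparin cofactor gene (1.08). Among the largest falls of such genes were ITGA11 (-2.40, SE 0.32), N4BP3 (-2.06), SELENOP (-2.03), NPTX1 (-1.92) and GIMAP5 (-1.92). Of 6 epithelial markers 2 were higher, with 3 higher and 1 lower adjusted over the list alone (median 0.11, camera adjusted p = 0.201, fry adjusted p = 0.00395). KRT7 of this list was at 1.196 and missed the threshold (adjusted p = 0.0566). KRT18 and KRT19 were at 0.27 and 0.39, NES of the podocyte list at 0.34, and RGS5 and ITGA8 of the mesangial list at 0.29 and -1.74. ITGA8 was low, with a mean of 0.594 CPM. By limma 0 of 5 fibroblast markers passed (0 adjusted over the list alone). Of the genes named here, CLU, ITGA8 and KRT18 lost the call without library 11 or 12, HPSE without 11, CFB without 11, 12, 13 or 18, NES without 11, 12 or 13, and KRT19 without 11, 12, 14, 17, 18 or 20. Their highest adjusted p, in that order, was 0.0556, 0.0782, 0.0746, 0.0567, 0.0794, 0.0882 and 0.105. TFPI2 and BGN lost it with all 18 libraries in 1 fit (0.130 and 0.119).

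The 72 h count depended on single libraries. Leaving out library 11, 12 or 13 without TA-TMA gave 488, 425 and 732 genes, leaving out TA-TMA library 18 or 20 gave 679 and 881, and leaving out library 19 gave 2219. Without library 17 it was 1566. All 18 libraries in 1 fit gave 2367 and quality weights, chosen after seeing the data, 3132. Tested against a fold of 1.2, 38 genes passed, and of the genes named here these were GDF6, ITGA11, GIMAP5, PECAM1, ICAM1, SULF2, PDGFB, ABCA1 and PDK4. Of 110 named genes past the threshold, 54 kept it with any 1 library left out, PECAM1, KDR, VWF, ICAM1, SULF2, PDGFB, COL4A1, HLA-B, PTTG1, GDF6, ITGA11 and GIMAP5 among them. CD34, MEST, N4BP3, SELENOP and NPTX1 did not, with highest adjusted p of 0.0607, 0.0813, 0.0811, 0.0581 and 0.0512. The highest came without library 11 for MEST and without library 12 for the other genes of these.

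**Figure D2:**
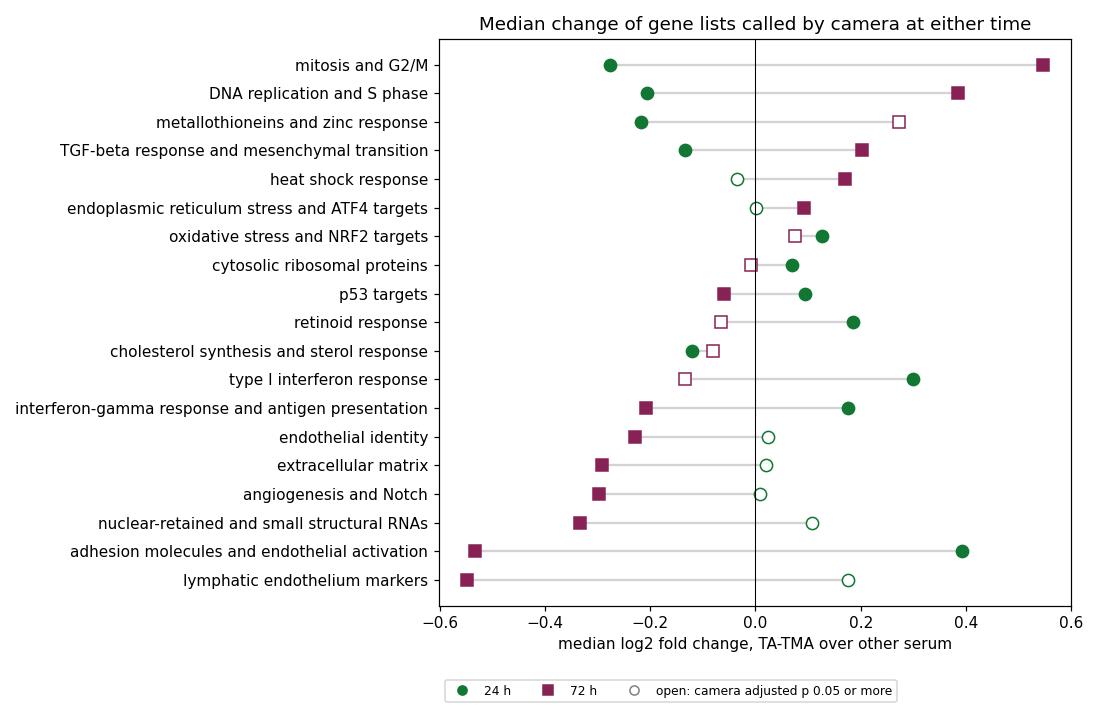
Median log2 fold change (horizontal axis) of the tested members of each list called by camera at 24 h (circles) or 72 h (squares), TA-TMA serum over serum without it, with open symbols where camera adjusted p was 0.05 or more. The mitosis median is -0.28 at 24 h and 0.55 at 72 h, and no call held with an estimated correlation.

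Whether the serum effect differed between the times was tested directly, and many genes did differ. PECAM1 was at 0.42 at 24 h and -0.90 at 72 h, a difference of -1.32 (SE 0.17, limma adjusted p = 3.47e-04), and HLA-B differed by -1.16 (adjusted p = 1.61e-04). KDR differed by -0.71, ICAM1 by -1.23 and VWF by -2.24, while PTTG1, BIRC5 and MT2A differed by 0.90, 0.89 and 0.65. Among the largest differences of genes with a mean of at least 1 CPM were KRT7 (2.11) and MEST (1.90) upward and ITGA11 (-2.96), GIMAP5 (-2.68) and the protease inhibitor gene A2M (-2.54) downward. Of 12961 genes, 846 had a higher and 806 a lower effect at 72 h than at 24 h. Across genes, which are not independent replicates, the log2 fold changes of both times correlated at -0.32 (Pearson) and -0.44 (Spearman). Of 1447 genes called at 72 h and fitted in both, 1278 had the opposite sign at 24 h, where 0 genes passed by limma. At 24 h 1010 genes had an unadjusted p under 0.05, and 628 with all 18 libraries in 1 fit.

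By list, mitosis genes differed upward in 22 of 30 members (median 0.81, camera adjusted p = 9.6e-17, and adjusted p = 0.219 with an estimated correlation). S phase genes did so in 14 of 28 (median 0.57, adjusted p = 4.3e-12, and 0.256 with an estimated correlation). Endothelial identity differed downward in 8 of 18 (median -0.29, adjusted p = 0.00244, and 0.172 with an estimated correlation). So did adhesion genes in 4 of 10 (median -0.87, adjusted p = 9.6e-04, and 0.172 with an estimated correlation) and antigen presentation genes in 9 of 19 (median -0.39, adjusted p = 3.3e-06, and 0.172 with an estimated correlation). Adjusted over the list alone the counts were 29, 26, 8, 7 and 11 in that order, with 3 endothelial identity genes and 1 adhesion gene going the other way. Camera called 14 of 37 lists here and 0 held with an estimated correlation (9 at an unadjusted p under 0.05), while fry called 16, with hypoxia and glycolysis, glucocorticoid response, nuclear-retained RNAs and epithelial markers among them without a camera call. Leaving out library 11 or 12 without TA-TMA at 72 h reduced the 1652 genes to 949 and 1067, a test against a fold of 1.2 gave 59, and quality weights gave 3184.

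**Figure D3:**
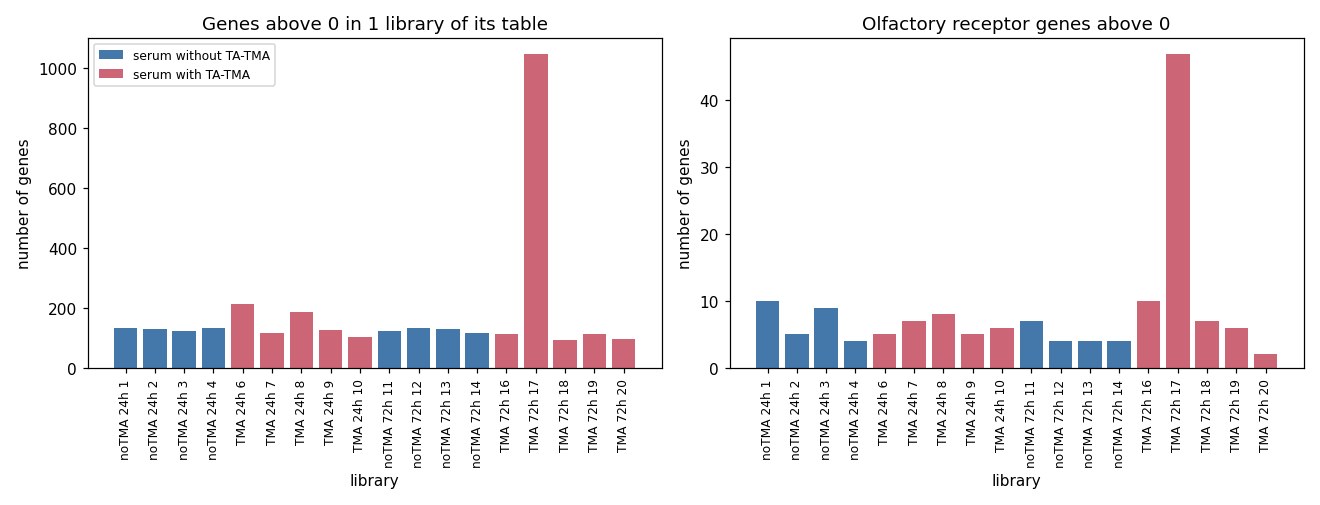
Number of genes above 0 in a single library of its table (left) and of olfactory receptor genes above 0 (right) in each of the 18 libraries, coloured by kind of serum. TA-TMA library 17 at 72 h stands at 1047 and 47 genes, and the other libraries at 72 h hold at most 132 and 10.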

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

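Of the tests in this part, those of 24 h gene counts, of background in library 17, of the share of endothelial cells, of RNA from another cell type and of genomic DNA were chosen after the result was seen.

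The 72 h difference was weighed against chance, technical bias and cell composition. Of 100 splits of the 9 libraries into 5 and 4, 2 called as many genes, the real one included (1453, highest other 2042). That makes chance unlikely for the gene count but does not exclude it. The split with 2042 genes, more than the real one, set TA-TMA library 19 with the 4 libraries without TA-TMA. For lists chance cannot be excluded either, since 8 of 100 splits called as many (13, highest other 16). Most of the other splits among these stayed close to the real grouping. They exchanged 1 library of each kind or, with 16 lists, set 1 TA-TMA library with the 4 libraries without TA-TMA. Removing length and GC trends kept 87.1% of the genes and leaving out library 17 kept 85.2%, which argues against both as the whole cause. For 5 endothelial identity genes (ENG, EGFL7, ESAM, FLT1 and SOX17) intervals lay above the list's median, so the list did not fall by the same amount throughout. That argues against a uniform loss of endothelial cells as the whole cause, and not against some loss beside other changes. What also stays open is the serum itself, its donors' other treatment and the density of the cultures.

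Of 1447 genes called at 72 h and fitted in both times, 1278 had the opposite sign at 24 h, where none was called by limma. Of 100 pairs of splits, only the real pair called as many as 1652 differing genes (highest other 236). Only the real pair gave a correlation as low as -0.323 (lowest other -0.276). A random regrouping of both times at once is therefore unlikely to give either result. The splits of both times were redrawn together, which generally also broke the 72 h grouping. The direction of the 24 h effect was not tested against a fixed 72 h effect. Chance is thus not excluded for that direction, nor for the opposite signs that rest on it. A candidate explanation is a growth state shared by libraries. Within groups at 24 h, each gene's correlation with the mitosis score was taken, with mitosis and S phase genes left out. Across genes, these values correlated with the 72 h change at 0.397 (Spearman), above 96 of 100 permuted scores. That result is borderline, since the highest permuted value was 0.434, and it does not say whether serum set the growth state. A wrong group or time label was not tested and stays open.

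TA-TMA library 17 at 72 h stood apart from the 4 others of its group in estimated reads (27.0 M), genes above 0 (17104), genes seen in it alone (1047) and olfactory receptor genes above 0 (47). Depth does not account for it, since after thinning to the others' median depth it still held 7.07 times the highest number of the others. The 10 most abundant of its own genes held 12.8% of these genes' reads, and 82.4% of its own genes had 1 or 2 reads. That argues against RNA of a cell type with a few abundant genes of its own. It does not cover genes that another cell type would share with these cultures, which were left out. Genomic DNA cannot be told apart from other sources, since olfactory receptor genes held 2.81 times the reads of the next library, between both bounds set for the test. No other biological explanation was tested.

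Single libraries lay far from the rest of their group in further values, and chance alone gives about 1 such group in 20, against 21 of 434 here. Library 1 at 24 h without TA-TMA was highest for ANGPT2 (3958) and lowest for CENPA (182), the mitosis score (9.83) and the S phase score (9.58, both mean log2 values), and library 3 was highest for RARRES3 (64.9). TA-TMA library 9 at 24 h was highest for TP53INP1 (1752). TA-TMA library 19 at 72 h was highest of its group for PECAM1 (14164), KDR (9676) and SULF2 (1572 normalized counts). At 72 h without TA-TMA, library 11 was highest for olfactory receptor genes (7), GATA3 (523) and RELN (310) and lowest for SERPINB2 (2754), library 12 highest for BIRC3 (60.8) and AHRR (941), and library 14 highest for IL6 (153) and PGK1 (9854).

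Genes whose serum effect differed between the times by limma are given as the 72 h minus the 24 h log2 fold change. Upward they were KRT7 (2.11), MEST (1.90), FAM239A (1.64), IL7R (1.59), LINC01483 (1.55), TGFBI (1.10), CCNB1 (0.95), PTTG1 (0.90), BIRC5 (0.89), FEN1 (0.70), MT2A (0.65), MCM4 (0.64), MT1L (0.61), HSPD1 (0.56), SKIL (0.56), MT1E (0.52), TYMS (0.44), HSP90AA1 (0.43) and AHSA1 (0.37). Downward they were RSAD2 (-4.25), ITGA11 (-2.96), GIMAP5 (-2.68), A2M (-2.54), N4BP3 (-2.42), HSD17B2 (-2.30), VWF (-2.24), NID1 (-1.88), BIRC3 (-1.49), PECAM1 (-1.32), IFIT2 (-1.31), LGALS9 (-1.24), ICAM1 (-1.23), IFIH1 (-1.16), HLA-B (-1.16), FLT4 (-1.06), LYVE1 (-1.01), NRP2 (-0.93), KDR (-0.71), TP53INP1 (-0.70), COL18A1 (-0.70), MMRN1 (-0.66), RELB (-0.65), TGFBR2 (-0.63), HLA-C (-0.59), FGF2 (-0.56), BTG2 (-0.54), MMP2 (-0.52), F11R (-0.46), PLK2 (-0.46) and TNIP1 (-0.29). With a library left out, 8 of these did not pass in some run: FAM239A, RELB, BIRC3, RSAD2, IFIH1, TGFBI, HSP90AA1 and MT1L, with highest adjusted p of 0.0905, 0.0904, 0.0851, 0.0795, 0.0828, 0.0620, 0.0614 and 0.0546. FAM239A, RELB, BIRC3, RSAD2, IFIH1 and HSP90AA1 also did not pass in 1 other setting each, with adjusted p of 0.0534, 0.0535, 0.0641, 0.0616, 0.0699 and 0.0536. The RSAD2 difference (SE 1.27) comes from low values, with a mean of 0.466 CPM at the time of its lower mean. RSAD2 did not pass at 72 h alone (limma adjusted p = 0.0550).

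List medians of the difference between the times, for lists called by camera and lost with an estimated correlation, were 0.81 for mitosis, 0.59 for metallothioneins, 0.57 for S phase, 0.35 for TGF-beta response and 0.20 for heat shock. They were -0.87 for adhesion, -0.66 for lymphatic markers, -0.41 for type I interferon, -0.39 for interferon-gamma and antigen presentation, -0.34 for matrix, -0.30 for NF-kB targets, -0.29 for endothelial identity, -0.27 for angiogenesis and Notch and -0.16 for p53 targets. The lowest adjusted p among these with an estimated correlation was 0.172. Of these lists fry did not call type I interferon (adjusted p = 0.426) and matrix (0.0814).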

How the results depend on the processing

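The settings chosen after seeing the data were both pseudocounts, trimmed-mean and quantile scaling, quality weights, the variance prior that is not robust, and removal of length and GC trends, and the pairing test was chosen after its result was seen. No setting turned the direction of a called gene. At 24 h the gene count was 0 in every setting, with 52 to 1421 genes at an unadjusted p under 0.05. At 72 h the 1453 genes became 2379 at an adjusted p under 0.10, 38 when tested against a fold of 1.2 (13.2% of them higher, against 46.0%), 2367 with all 18 libraries in 1 fit and 3132 with quality weights, and 425 to 2219 with a library left out. For the difference between times the 1652 genes became 2763, 59 and 3184 at 0.10, against 1.2-fold and with quality weights, and 949 to 2469 with a library left out. The filters, pseudocounts, scalings, prior and trend removal gave 1066 to 1505 and 1468 to 1711 genes. The causes were not tested, apart from the looser and the stricter threshold.

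Camera with an estimated correlation called 0 lists at 24 h and 0 at 72 h (4 and 7 at an unadjusted p under 0.05), against 12 and 13, and fry called 3 and 15. Of the camera calls at 72 h, TGF-beta response, p53 targets and endoplasmic reticulum stress were not called by fry (adjusted p of 0.0984, 0.0887 and 0.0521). With a library left out camera called 10 to 14 lists at 24 h and 9 to 15 at 72 h. Of named-gene values with a library left out, 182 lost the call and 31 gained it at 72 h, and 67 lost it for the difference between times. Under other settings 130 lost and 59 gained it at 72 h, and 46 lost it for the difference.

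No paired analysis was possible because TA-TMA and other serum share no library number at either time. For the difference between times a block joining label number n at 24 h with n + 10 at 72 h, which the labels do not state, gave 2758 genes, 1635 of the 1652 among them. The main fit used no such block, since the labels do not state the pairing. Single pairs correlated weakly, at 0.0607 to 0.222, with 6 of 9 over 0.1. Their mean of 0.145 was above 99.97% of 2880 pairings within groups (exact one-sided p = 3.5e-04). The highest other mean was 0.141, so the bound set for the test was met. Of 9 libraries 6 correlated best with their own number. Both are a hint from the data that libraries n and n + 10 may share a serum. If they do, the main fit of the difference treated paired libraries as independent.

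The DESeq2, voom, sva and edgeR relative-log-expression alternatives and both comparisons between times in the same serum were planned and not run. DESeq2 and voom need counts, and the comparisons between times need a shared scale. With 4 and 5 libraries, simulated 1.5-fold changes were called in 67.0% of genes at either time, so smaller changes can be missed.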

Other observations

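The tests in this part with the mitosis score as a covariate and of 24 h gene counts were chosen after the result was seen.

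Further lists had members past the limma threshold at 72 h without a camera call, among them NF-kB targets, hypoxia and glycolysis and lipid genes, which fry called (adjusted p of 0.0258, 0.00340 and 0.0241). Counts near 11.1%, the share of all genes tested that passed, do not set a list apart. Among genes of KLF2, KLF4 and laminar flow, 4 of 13 were lower and 1 higher (2 higher and 4 lower adjusted over the list alone), the natriuretic peptide receptor gene NPR1 at -1.02, the water channel gene AQP1 at -1.63 and the arginine transporter gene SLC7A2 at 0.58. Of NF-kB targets 3 of 14 were lower (5 adjusted over the list alone), TNFAIP2 at -0.43 and BIRC3 at -1.13. Oxidative stress genes had 4 of 22 higher (6 higher and 1 lower adjusted over the list alone), SRXN1 at 0.40 and GCLM at 0.35, and hypoxia and glycolysis genes 3 of 22 higher and 2 lower (6 and 2), the lactate dehydrogenase gene LDHA at 0.36 and PGK1 at 0.29. Apoptosis regulators had 2 of 23 higher and 4 lower (3 and 4), among them BMF at -0.87. Of sterol genes 3 of 29 were lower and of lipid genes 2 of 16, both counts the same adjusted over the list alone, with SREBF2 at -0.40 and SCD at -0.42. Retinoid genes had 2 of 11 higher, RARB at 0.57 and RARG at 0.40, and the list's median (-0.07) and mean (0.20) differed in sign. AQP1, SLC7A2, TNFAIP2, BIRC3, GCLM, PGK1, SREBF2, SCD, RARB and RARG did not pass in some run with a library left out, with highest adjusted p of 0.0666, 0.0529, 0.0528, 0.0991, 0.0625, 0.0586, 0.104, 0.0920, 0.0815 and 0.0791, each without library 11 or 12. With all 18 libraries in 1 fit AQP1, SRXN1, SREBF2, SCD and RARB did not pass (0.0824, 0.0614, 0.0519, 0.141 and 0.144), nor did SCD with length and GC trends removed (0.0622).

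The mean log2 value of the mitosis genes was 9.64 ± 0.19 (SD, n = 4) without TA-TMA and 10.19 ± 0.24 (n = 5) with it at 72 h (exact permutation test, two-sided, p = 0.0159), and 10.14 ± 0.21 and 9.86 ± 0.31 at 24 h (same exact test, p = 0.167). With this score as a covariate limma called 0 genes at 72 h, with 1686 at an unadjusted p under 0.05, against 1453 called and 3638 without it. The score separated both kinds of serum at 72 h and is itself an outcome, so this does not tell a growth effect from a serum effect.

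At 24 h chance cannot be excluded for lists, since 9 of 100 splits called as many as the real 12 (highest other 16). For genes the splits decide nothing, since all 100 must reach the real count of 0 by limma (highest other 132). The split with 132 genes set libraries 1, 2, 6 and 7 against 3, 4, 8, 9 and 10, across both kinds of serum. What divides these libraries was not tested. In the real groups 1010 genes had an unadjusted p under 0.05, and 666 without library 2, where 659 of all genes tested would by chance.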
